A study of Drosophila melanogaster with 6 samples.

How the data were processed

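Total RNA of Drosophila melanogaster S2R+ cells, an established embryonic cell line, was sequenced after ribosomal RNA depletion with TGIRT-seq. This method copies RNA with a thermostable group II intron reverse transcriptase, which reads through structured and modified RNAs such as snoRNAs and tRNAs, so that small and long RNAs are measured in 1 library. Per the labels, 3 libraries came from cells given double-stranded RNA against bacterial lacZ (dsLacZ, the control) and 3 from cells given double-stranded RNA against Fibrillarin (dsFib). The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

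The deposited tables give, per gene, an estimated count, a CPM and a TPM, per the file headers. The submitters' processing notes name cutadapt 3.4, Bowtie2, STAR and the genome build dm6, without roles or order. The names of the deposited tables name CoCo as the counter, whose version, annotation and filters are not given in the sources used here. The estimated counts deposited by the authors are not all whole numbers: between 7.19% and 9.36% of the genes in a library had a fractional value. Reads of near-identical copies (tRNA genes, snoRNA copies, transposable elements) can be split between them in counting, so their values are uncertain copy by copy. The deposited CPM equals the estimated count divided by the library's total and scaled to CPM, with a largest difference of 1.5e-11. The deposited TPM is scaled by the authors to a fixed total, per the file headers, and was not used for tests. Each table held 23932 genes, of which 23851 were found by identifier in the Ensembl annotation of BDGP6, which has the coordinates of dm6.

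Counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 8302, libraries were scaled by TMM, and the groups were compared with the quasi-likelihood test in a model with the group as its single term. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Expression is given as TMM-scaled CPM, as mean ± SD over 3 libraries, and fold changes are those of the edgeR model, libraries labelled dsFib over dsLacZ, with the standard error (SE) of the log2 fold change. Values of single measures per library were compared with a two-sided exact permutation test, for which 3 libraries against 3 allow no p below 0.1. Depth was 11695250 to 15172052 counts per library. In counts simulated for this comparison over 8302 genes, edgeR recovered 18 of 67 genes changed 1.5-fold, 48 of 67 changed 2-fold and 52 of 66 changed 4-fold, with 4 false calls among 122. The simulation drew genes independently, without shifts shared by a whole library, so these rates may not carry over to the real libraries.

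Box C/D and box H/ACA snoRNAs were told apart by a pattern of gene names fixed beforehand, which put 137 genes of the tables in the box C/D class and 114 in the box H/ACA class. It left genes named Or-ACA (in capitals) and snR38 in neither, and no Or-ACA gene passed the filter on low counts. A host was the gene of the annotation that holds the snoRNA on the same strand. The 32 gene lists, 31 of them fixed as lists of names and 1 of host genes, were tested with camera from limma 3.58.1 on voom values with its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists that had at least 2 tested members. Camera with an estimated correlation and fry were run beside it. Values of fry are those of its directional form unless its mixed form, which ignores direction, is named.

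The rule for named genes took the core box C/D protein genes and Nop60B in every case. Of genes outside the small RNA classes it took the 10 largest rises and the 10 largest falls past the threshold with a mean CPM of at least 5 and no overlap between the groups. It also took the 4 largest falls and the 3 most abundant of the box C/D snoRNAs, and the 3 members of each other list with the smallest p. Fewer than 10 rises other than Fib are therefore named, since Fib is among the 10. Genes named outside this rule, picked after their values were seen, are the hosts and neighbours of snoRNAs (RpL15, RpL28, RpS9, RpS16, Sf3b3, Uhg4, dom, CG10576 and CG1646), snoRNA:229, snoRNA:684 and snoRNA:291, and those that the text says were picked in this way.

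Alternatives were other normalisations (DESeq2's size factors in edgeR, total counts alone, and TMM on genes outside the small RNA classes), other tests (DESeq2 1.42.0, limma-voom, and glmTreat against a 1.5-fold change), no filter on low counts and a minimum mean count of 10. Others were a model with the replicate number as a block, and leaving out each library in turn. The test, the named-gene rule, the lists and these alternatives were fixed before the data were examined. Voom with quality weights per library and wider name classes of snoRNAs were added after seeing the data. The class ratio and share without U3 were not in the plan fixed beforehand. Within each group, no pair of libraries agreed within sampling noise (chi-square of their counts per degree of freedom 11.6 or more), so none was taken for a repeat deposit of another library; this does not tell separate cultures from separate libraries of 1 culture. Figures and tables were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1, NumPy 2.4.6 and Matplotlib 3.10.9.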

Results

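RNA of S2R+ cells was profiled in 6 TGIRT-seq libraries, 3 from control cells that received double-stranded RNA against lacZ and 3 from cells in which Fibrillarin, the methyltransferase of box C/D snoRNA particles, was targeted by RNA interference. Box C/D snoRNAs guide 2′-O-methylation of ribosomal and spliceosomal RNA, and box H/ACA snoRNAs, whose particles hold no Fibrillarin, guide pseudouridylation. The libraries held 12235192, 13327810 and 13617114 counts in dsLacZ replicates 1, 2 and 3, and 11695250, 12827749 and 15172052 in those labelled dsFib replicates 1, 2 and 3. Protein-coding mRNA took 55.0% ± 6.61 of the counts in dsLacZ and 55.3% ± 2.54 in the libraries labelled dsFib (mean ± SD, n = 3). Nuclear tRNA took 13.4% ± 4.25 and 14.5% ± 1.01. One control library stood apart: dsLacZ replicate 2 had 18.3% of its counts in nuclear tRNA, against 10.8% and 11.1% in the other dsLacZ libraries, and it lay farthest out on the first principal component, which held 42.8% of the variance.

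The first question was whether Fib, the targeted gene, was lower in the cells given double-stranded RNA against it. Fib (FBgn0003062; 2R, 23072909 to 23074725, minus strand, dm6) was instead 4.67-fold higher in the libraries labelled dsFib. Its level was 213.9, 257.4 and 227.4 CPM in dsLacZ replicates 1, 2 and 3, and 1312, 954.9 and 994.3 CPM in the libraries labelled dsFib. The log2 fold change was 2.22 (SE 0.15, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00103, n = 3 per group), and all 3 libraries labelled dsFib lay above all 3 control libraries. The targeted gene thus went against the label, and every direction below is that of the libraries labelled dsFib against dsLacZ. Genes of the other core proteins of box C/D particles had log2 fold changes close to 0: -0.01 for Nop56 (SE 0.09), -0.01 for nop5 (SE 0.10) and 0.05 for hoip (SE 0.11). Nop60B, the pseudouridine synthase of box H/ACA particles, had 0.04 (SE 0.13). The assembly factors pont and rept had -0.13 and -0.12. Among the 8 genes listed for box C/D proteins and assembly, Fib alone changed (DESeq2 and limma-voom also called 1), and the list's median log2 fold change was -0.07 while its mean, which Fib carries, was 0.19. The list did not pass the set test (camera adjusted p = 0.728).

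**Figure D1:**
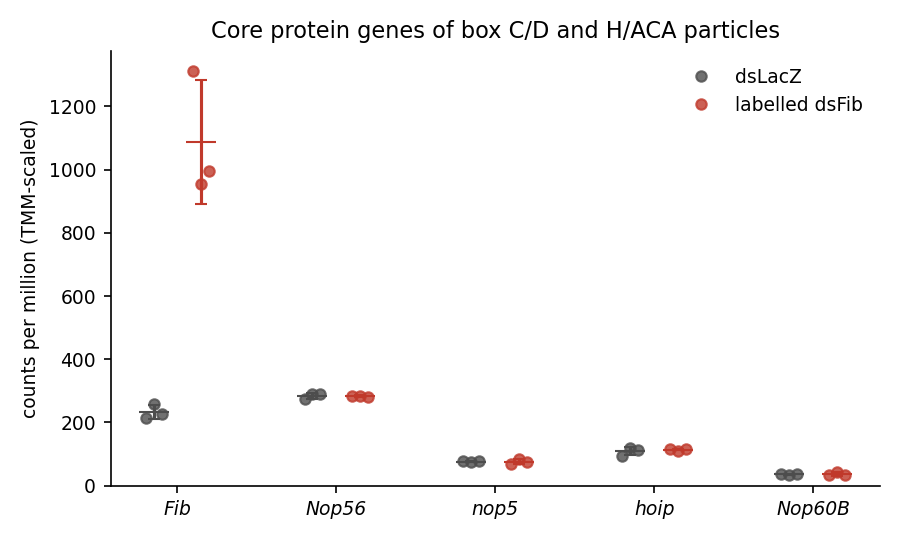
TMM-scaled CPM of Fib, Nop56, nop5, hoip and Nop60B in each library (points), with the mean and SD of 3 libraries per group (bars). Fib is at 213.9 to 257.4 CPM in the 3 dsLacZ libraries and at 954.9 to 1312 CPM in the 3 libraries labelled dsFib, while the groups of the other genes lie together.

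The second question was what became of box C/D snoRNAs. They were lower as a class in the libraries labelled dsFib: of 88 tested, 77 had a log2 fold change below 0, 15 fell and 0 rose, and the median was 1.70-fold lower (log2 -0.77). None was higher at an unadjusted p of 0.05, by DESeq2 or by limma-voom. Adjusted over the list alone, 48 fell. The groups did not overlap for 45 of them, all lower in the libraries labelled dsFib, against 1006 lower and 916 higher of all 8302 genes tested. The deepest fall was that of snoRNA:Me18S-G1358c, a guide for 18S rRNA encoded in RpL15 (3L, 27267383 to 27267450, plus strand, overlapping an annotated exon), from 1048 ± 374.6 to 136.2 ± 27.7 CPM, or 7.69-fold (adjusted p = 0.00515). In an intron of the same host, snoRNA:Me18S-C419 fell 5.33-fold (adjusted p = 0.0278). The orphan snoRNA:Or-CD11b in RpL28 fell 4.68-fold (adjusted p = 0.0185), and snoRNA:Me28S-G3253 in an intron of RpS9 fell 3.29-fold (adjusted p = 0.00672). The hosts RpL15, RpL28 and RpS9 did not pass the test, with log2 fold changes of -0.08 (SE 0.11), 0.56 (SE 0.26) and -0.08 (SE 0.13).

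Guides for both large ribosomal RNAs were among them. Of 18 tested guides for 18S rRNA, 17 lay below 0 and 3 fell, with a median log2 fold change of -0.86. Of 45 guides for 28S rRNA, 40 lay below 0 and 8 fell, with a median of -0.76. These 8 include the 3 copies of snoRNA:Me28S-A2589 in dom, which may share reads. All 8 tested orphans, which have no known target, lay below 0 and 3 fell, with a median of -1.05. Of these orphans, the 3 most abundant were picked after their values were seen: snoRNA:Or-CD12, with 1730 ± 262.1 and 998.9 ± 192.7 CPM, did not pass (adjusted p = 0.0774), snoRNA:Or-CD1 fell from 1091 ± 203.2 to 521.3 ± 15.5 CPM and snoRNA:Or-CD2 from 930 ± 236.6 to 352.3 ± 59.8 CPM. U3, which acts in cleavage of the ribosomal RNA precursor and not in methylation, was the exception among abundant box C/D snoRNAs. Its 3 genes, which share reads, had log2 fold changes of 0.06 for snoRNA:U3:9B (SE 0.19), -0.07 for snoRNA:U3:54Aa (SE 0.17) and 0.36 for snoRNA:U3:54Ab (SE 0.18). None of the 3 passed the edgeR test, an unadjusted p of 0.05, DESeq2 or limma-voom. The U3 genes also lie in no host and are 210 to 213 nucleotides long, against a median annotated length of 80 for the class. Function, host and length thus cannot be told apart here.

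Camera with the preset correlation placed the box C/D list below other genes with an adjusted p of 5.39e-20, the 18S guides with 1.53e-08 and the 28S guides with 9.89e-15. With an estimated correlation, each had an adjusted p = 0.464, and none of the 3 passed fry in its directional form (adjusted p of 0.102 or more). The mixed form of fry, which does not test a direction, gave adjusted p-values of 0.0195, 0.015 and 0.021. The number of box C/D snoRNAs past the threshold depended on the library left out: it was 35, 31 and 1 without dsLacZ replicates 1, 2 and 3, and 0, 1 and 0 without dsFib replicates 1, 2 and 3, with medians between -0.99 and -0.54, while DESeq2 called 37. Levels were often highest in dsLacZ replicate 2, as for snoRNA:Me18S-G1358c with 1468 CPM there against 748.1 and 927.3 CPM in the other dsLacZ libraries, and without that library the class median was -0.54.

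Box H/ACA snoRNAs served as the comparison class within the same libraries, and the list showed no such shift with all 6 libraries. Of 108 tested, 0 passed the edgeR test, 53 lay above 0 and 55 below, and the median log2 fold change was near 0 under each scaling (-0.001 with TMM, 0.01 with DESeq2's size factors). At an unadjusted p of 0.05, 3 were higher and 5 lower; DESeq2 called 1 higher and limma-voom 0. The smallest p-values belonged to snoRNA:Psi18S-640b, snoRNA:Psi28S-1135f and snoRNA:Psi18S-640a, with log2 fold changes of -0.48, 0.40 and -0.42 and adjusted p-values of 0.122, 0.125 and 0.155. Camera gave the list an adjusted p of 0.908, but the list passed without dsLacZ replicate 1 (median -0.11, adjusted p = 0.00136) and, in the other direction, without dsLacZ replicate 2 (median 0.13, adjusted p = 8.40e-04). These are values at the preset correlation. With all 6 libraries and an estimated correlation, camera gave an adjusted p of 0.989.

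**Figure D2:**
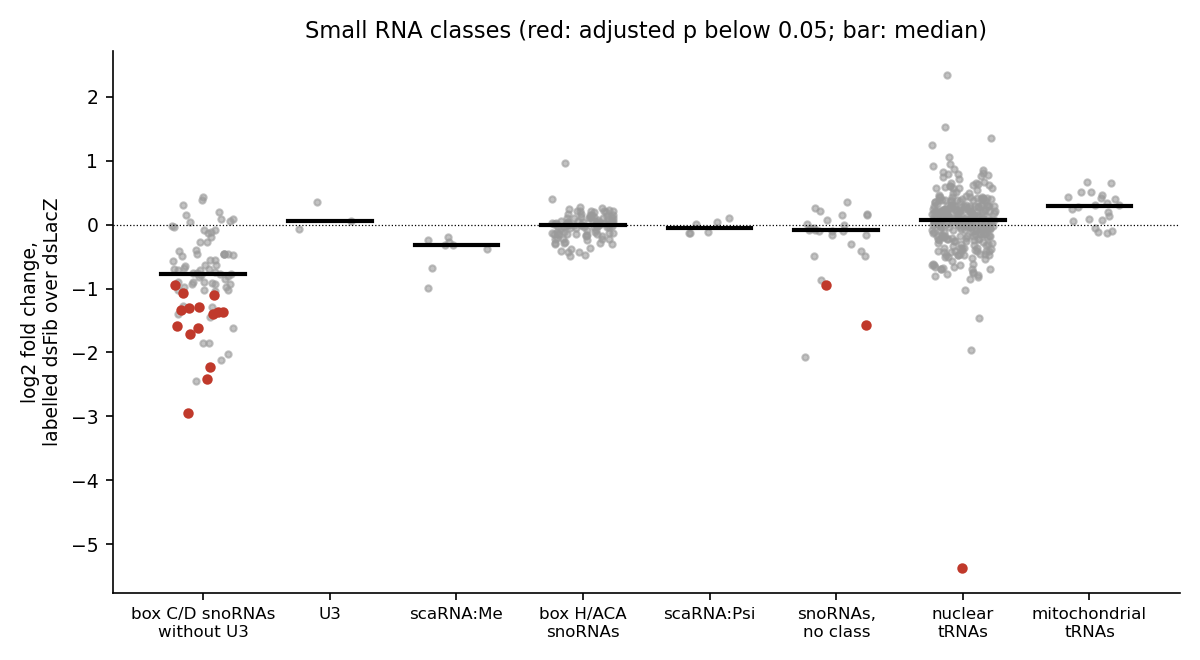
Log2 fold change of each tested small RNA, libraries labelled dsFib over dsLacZ, by class. Red points pass an adjusted p of 0.05, and black bars are class medians. Box C/D snoRNAs without U3 have a median of -0.78, while U3, box H/ACA snoRNAs and nuclear tRNAs have medians of 0.06, -0.001 and 0.07.

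The ratio of the classes within a library does not depend on how libraries are scaled. The log2 ratio of box C/D to box H/ACA counts was -0.66 ± 0.06 in dsLacZ and -0.88 ± 0.05 in the libraries labelled dsFib (n = 3 each), and every library labelled dsFib lay below every dsLacZ library. The exact permutation test gave p = 0.1, the smallest that this design allows. U3 held most box C/D counts, and without it the ratio went from -2.19 ± 0.09 to -3.19 ± 0.03, a difference of -1.004, again with an exact p of 0.1. The planned ratio and share were those of the whole class. The versions without U3 were not in the plan, and they leave out 3 genes that were not lower. As a share of the library, box C/D snoRNAs took 3.04% ± 0.28 of counts in dsLacZ and 2.58% ± 0.24 in the libraries labelled dsFib (exact p = 0.2). Without U3 the shares were 1.06% ± 0.13 and 0.521% ± 0.034 (exact p = 0.1), and U3 alone took 1.98% ± 0.16 and 2.06% ± 0.21 (exact p = 0.6).

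**Figure D3:**
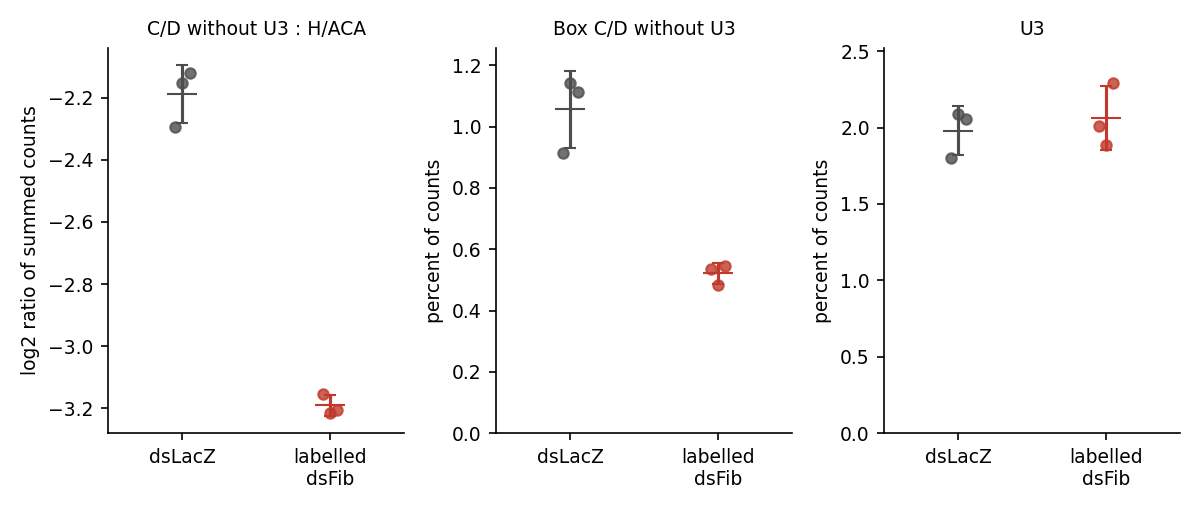
Per-library log2 ratio of box C/D counts without U3 to box H/ACA counts (left), and percent of counts in box C/D snoRNAs without U3 (middle) and in U3 (right). Points are libraries, bars the mean and SD of 3. The groups are apart in the first 2 panels and overlap for U3, at 1.98% and 2.06% of counts. With U3 included, the ratio (not shown) was -0.66 ± 0.06 in dsLacZ and -0.88 ± 0.05 in the libraries labelled dsFib.

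Most fly box C/D snoRNAs lie in introns, either of protein-coding genes or of Uhg genes, whose spliced RNA has no known protein product. Levels were lower in both settings. The 40 tested box C/D snoRNAs in protein-coding hosts had a median log2 fold change of -0.95, with 37 below 0 and 10 that fell. The 39 in Uhg hosts had a median of -0.71, with 33 below 0 and 5 that fell. The 4 tested with no host, the 3 U3 genes among them, had a median of -0.007, with 2 below 0 and 0 that fell. Whether these groups differ was not tested. The host RNAs showed no such fall by median: of 35 tested host genes, 0 passed the edgeR test (limma-voom 0, DESeq2 3 higher), 23 lay above 0, and the median was 0.09. The 28 tested protein-coding hosts had a median of 0.14. The 6 tested Uhg genes had a median of -0.02, with 3 below 0 and a lowest value of -0.54, and 0 passed the edgeR test. At an unadjusted p of 0.05, 8 hosts were higher and 2 lower. The host genes with the smallest p were RpL13A, CG45050 and RpL3, with log2 fold changes of 0.51, 0.54 and -0.37 and adjusted p-values of 0.0624, 0.0977 and 0.214. As a list, the hosts had a camera adjusted p of 0.0599 (0.427 with an estimated correlation), and passed fry toward higher levels (adjusted p = 0.0264).

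A comparison within hosts was possible in 5 genes that hold tested snoRNAs of both classes. In dom, which encodes a chromatin remodeller, 3 box C/D snoRNAs had a median log2 fold change of -1.37 and 12 box H/ACA snoRNAs a median of 0.04. In RpS16 the single box C/D snoRNA had -1.62, and 4 box H/ACA snoRNAs a median of 0.001. Uhg4 gave -0.95 and 0.05, and RpL3 gave -0.78 and 0.14. Sf3b3 went the other way, with 0.38 for its single box C/D snoRNA and 0.05 for 3 box H/ACA snoRNAs. By median, box C/D snoRNAs were thus the lower class in 4 of the 5 hosts. Box C/D snoRNAs past the threshold were 3 of 3 in dom, 1 of 1 in RpS16 and 3 of 5 in Uhg4, and 0 of 3 in RpL3 (1 lower at an unadjusted p of 0.05) and 0 of 1 in Sf3b3. RpL3 itself had -0.37.

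Guides of the Cajal body and other small RNAs were compared in the same way. All 8 tested scaRNA:Me genes, which guide methylation of spliceosomal RNAs, lay below 0, with a median log2 fold change of -0.32. None passed the edgeR test, 3 were lower at an unadjusted p of 0.05, DESeq2 called 2 lower and limma-voom 0. The 3 with the smallest p were scaRNA:MeU5-C46, scaRNA:MeU4-A65 and scaRNA:MeU2-48, at -0.67 (adjusted p = 0.0863), -0.99 (adjusted p = 0.0933) and -0.38 (adjusted p = 0.128). The 6 scaRNA:Psi genes had a median of -0.05. The scaRNA list held 16 tested genes, among them snoRNA:MeU6-A47 and snoRNA:MeU6-C68, which also count in the box C/D class. This list had a camera adjusted p of 0.0518. Of 31 snRNA genes, 0 passed edgeR, DESeq2 or limma-voom, 1 was higher at an unadjusted p of 0.05, and the median was 0.04 (camera adjusted p = 0.273). Nuclear tRNAs had a median of 0.07 over 288 genes (camera adjusted p = 0.0715), of which 1 fell: tRNA:Lys-TTT-2-2, from 72.6 ± 49.4 to 1.81 ± 1.57 CPM (adjusted p = 0.024), a value that is uncertain because copies of this tRNA share reads. At an unadjusted p of 0.05, 20 nuclear tRNAs were higher and 20 lower, DESeq2 called 5 higher and 7 lower, limma-voom 0, and voom with quality weights 32 higher and 3 lower. The tRNA list passed camera without dsLacZ replicate 2 (adjusted p = 1.02e-30) and without dsFib replicate 2 (adjusted p = 0.00132), both at the preset correlation. With all libraries and an estimated correlation, camera gave it an adjusted p of 0.899. The 22 mitochondrial tRNAs had a median of 0.29, with 18 above 0 and 0 past the edgeR test (1 at an unadjusted p of 0.05, DESeq2 0, limma-voom 0).

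Outside the small RNA classes, 44 genes rose and 13 fell, so that 75 of 8302 genes changed in all, 44 higher and 31 lower. An unadjusted p of 0.05 was passed by 1323 of the 8302 genes, the share against which such counts in single lists are to be read. Fib was the largest of the rises that the rule names. It was followed by hwt (3.31-fold, adjusted p = 0.0329), by DOR, a nuclear receptor coactivator with a role in autophagy (2.89-fold, adjusted p = 0.00672), and by the transcription factor gene bab2 (2.65-fold, adjusted p = 0.0329). The next were lncRNA:CR46489 (2.45-fold), rho, a protease that releases EGF receptor ligands (2.36-fold), rdog (2.31-fold), the glutathione S-transferase GstD5 (2.09-fold) and CG3448 (2.06-fold). A transposable element copy, RR48391, was 2.16-fold higher (adjusted p = 0.0463), with reads that other copies may share. Abundant genes among the rises, picked after their values were seen, were Arc1, whose protein forms capsids (1198 ± 142.6 to 2174 ± 151.2 CPM), and the glutathione enzyme genes Gclc (98.9 ± 8.18 to 155.2 ± 11.3 CPM) and GstE6 (189.4 ± 17.3 to 301.4 ± 5.4 CPM).

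The largest fall outside the small RNA classes was that of snmRNA:CR43603, a small noncoding RNA encoded in an intron of CG10576 (3L, 5764861 to 5765046, minus strand). Its level went from 257.5 ± 35.4 to 53.6 ± 5.64 CPM, or 4.80-fold lower (adjusted p = 6.13e-04). The other falls were smaller. Ude, a uracil-DNA degrading factor, fell 1.91-fold (adjusted p = 0.0217) and SecS, which makes selenocysteinyl-tRNA, also 1.91-fold (adjusted p = 0.0384). CG31937 fell 1.86-fold, the PHD finger gene Phf7 1.75-fold, CG1635 1.70-fold, and dah, which acts in cellularisation of the embryo, 1.66-fold. The list ended with pigeon at 1.65-fold, the glycerol kinase gene Gk2 at 1.58-fold and yem, a histone H3.3 chaperone, at 1.53-fold. TER94, the fly p97 ATPase, was an abundant fall picked after its value was seen, from 646.2 ± 42.4 to 425.8 ± 13.2 CPM.

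These counts of genes were sensitive to single libraries and to scaling. Without dsLacZ replicates 1, 2 and 3 they were 55 higher and 58 lower, 221 and 89, and 1 and 2, and without dsFib replicates 1, 2 and 3 they were 1 and 1, 4 and 3, and 1 and 1. Scaling by total counts alone gave 5 higher and 26 lower, so that 16.1% of calls were higher against 58.7% with TMM.

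Genes of the translation machinery lay above 0 as a group. Of 85 cytosolic ribosomal protein genes tested, 75 had a log2 fold change above 0, with a median of 0.25, and 1 rose past the threshold over all genes, RpL17 (1.43-fold, adjusted p = 0.0426); adjusted over the list alone, 10 rose and 0 fell. DESeq2 called 14 higher and 0 lower, limma-voom 2 higher and 0 lower, and at an unadjusted p of 0.05, 37 were higher and 2 lower. RpL19 and RpL13 had log2 fold changes of 0.51 each, with adjusted p-values of 0.0546 and 0.0601. The list passed camera with an adjusted p of 1.08e-12, and had an adjusted p = 0.393 with an estimated correlation. Of 42 translation factor genes, 29 lay above 0, with a median of 0.12 (camera adjusted p = 0.0187, adjusted p = 0.102 with total counts alone, and adjusted p = 0.393 with an estimated correlation). None of these passed edgeR, DESeq2 or limma-voom, with 7 higher and 1 lower at an unadjusted p of 0.05. Of 37 nucleolar ribosome biogenesis genes, 24 lay above 0, with a median of 0.13 (camera adjusted p = 0.0369, and adjusted p = 0.464 with an estimated correlation). None passed edgeR, DESeq2 or limma-voom, with 6 higher and 1 lower at an unadjusted p of 0.05, and the members with the smallest p were CG13097 at -0.29, Nnp-1 at 0.28 and Non1 at 0.29. This list no longer passed camera without dsFib replicate 2 (adjusted p = 0.125), without dsLacZ replicate 1 (adjusted p = 0.145) or with total counts alone (adjusted p = 0.151). Precursor ribosomal RNA took 0.609% ± 0.003 of counts in dsLacZ and 0.485% ± 0.053 in the libraries labelled dsFib (exact p = 0.1), after depletion of ribosomal RNA.

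In the list of apoptosis, p53 and Xrp1 response genes, 12 of 14 lay above 0, with a median log2 fold change of 0.32, and 1 rose: Xrp1, a bZIP transcription factor gene of the response to ribosomal protein loss, from 145.4 ± 28.2 to 293 ± 40.1 CPM (2.01-fold, adjusted p = 0.0329). Irbp18, which encodes its partner, was at 0.45 (adjusted p = 0.149) and Gadd45 at 1.15 (adjusted p = 0.158). Adjusted over the list alone, 3 rose and 0 fell, and DESeq2 called 2 higher and limma-voom 1. At an unadjusted p of 0.05, 6 were higher and 0 lower. Camera gave the list an adjusted p of 0.00351, and there was an adjusted p = 0.464 with an estimated correlation. Of 32 cell cycle and DNA replication genes, 25 lay below 0, with a median of -0.22 (camera adjusted p = 1.95e-04, and adjusted p = 0.393 with an estimated correlation). None passed edgeR, though 12 were lower at an unadjusted p of 0.05, DESeq2 called 3 lower and limma-voom 0. Mcm5, Mcm3 and aurA had log2 fold changes of -0.50, -0.61 and -0.50, with adjusted p-values of 0.0573, 0.064 and 0.077. Without dsFib replicate 1, dsLacZ replicate 3 or dsFib replicates 2 or 3, Xrp1 no longer passed the threshold, at adjusted p-values of 0.212, 0.141, 0.14 and 0.096.

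Mitochondrially encoded mRNAs were lower as a list, with 11 of 13 below 0 and a median of -0.31 (camera adjusted p = 7.21e-05, and adjusted p = 0.464 with an estimated correlation). None passed edgeR, 8 were lower at an unadjusted p of 0.05, DESeq2 called 1 lower and limma-voom 0. The smallest p was that of mt:ND1, at -0.75 (adjusted p = 0.0546), followed by mt:ND3 at -0.62 and mt:ATPase8 at -0.32. Their share of counts was 2.25% ± 0.08 in dsLacZ and 1.77% ± 0.02 in the libraries labelled dsFib (exact p = 0.1). Nuclear oxidative phosphorylation genes showed no such shift, with a median of -0.006 with TMM and -0.04 with total counts alone, and a camera adjusted p of 0.76. The difference between these lists was not tested.

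**Figure D4:**
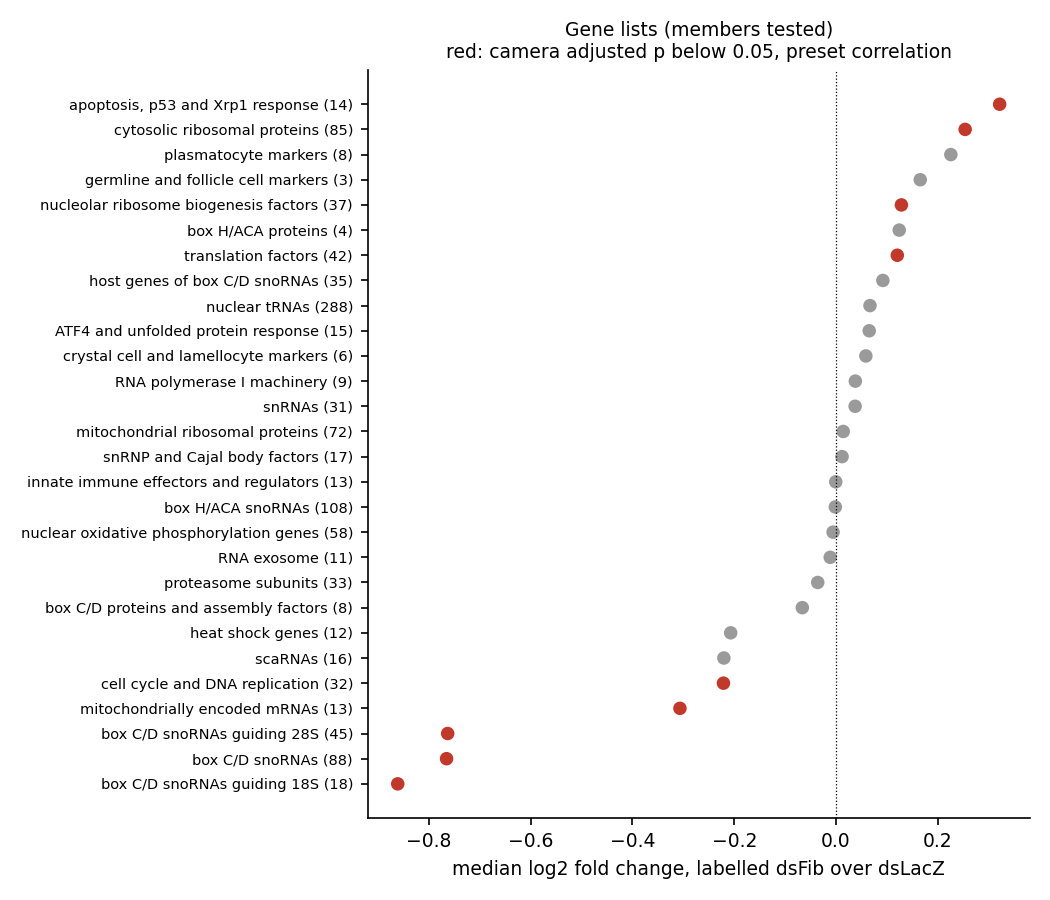
Median log2 fold change of each gene list with more than 2 tested members, libraries labelled dsFib over dsLacZ, with the number of members tested in parentheses. The 9 red lists passed camera with the preset correlation, and 0 lists passed with an estimated correlation.

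The remaining lists did not pass camera. Among innate immune genes, 1 of 13 rose in edgeR, Socs36E, an inhibitor of JAK/STAT signalling (1.64-fold, adjusted p = 0.0477). The genes cact and pirk were at 0.52 and 0.73 (adjusted p = 0.064 and 0.0997). Adjusted over the list alone, 4 rose and 0 fell, and DESeq2 called 4 higher and limma-voom 1. At an unadjusted p of 0.05, 4 were higher and 1 lower. The list's median was -0.0005 with TMM and -0.06 with total counts alone. Its mean was 0.15, and its camera adjusted p was 0.171. Heat shock genes had a median of -0.21 (adjusted p = 0.273), with Hsp68, DnaJ-1 and Hsp26 at -0.52, -0.26 and 0.60. ATF4 and unfolded protein response genes had a median of 0.07 (adjusted p = 0.586), with AsnS at -0.37, crc at 0.43 and PEK at 0.40. RNA polymerase I genes had a median of 0.04 and a mean of -0.03 (adjusted p = 0.586). None of the 9 passed edgeR, DESeq2 or limma-voom, with 0 higher and 3 lower at an unadjusted p of 0.05: CG3756 at -0.32, CG11417 at -0.36 and TAF1B at -0.31. Exosome genes had a median of -0.01 (adjusted p = 0.586) and Csl4 was at 0.50 (adjusted p = 0.0726). For snRNP and Cajal body factors the adjusted p was 0.989, for mitochondrial ribosomal proteins 0.586, for proteasome subunits 0.939 and for box H/ACA proteins 0.399. Of the replication-dependent histone genes, 1 passed the filter on low counts, so that no set test was made.

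Markers of other cell types gave no sign of a shift in cell type that passed a test. Plasmatocyte markers, the blood cell type closest to S2R+ cells, had a median of 0.23 over 8 genes (camera adjusted p = 0.101), with Hml at 0.89 (adjusted p = 0.224). Crystal cell and lamellocyte markers had a median of 0.06 over 6 genes (adjusted p = 0.399), germline and follicle cell markers 0.17 over 3 genes (adjusted p = 0.905), neuron markers 0.38 over 2 genes (adjusted p = 0.85) and muscle markers 0.46 over 2 genes (adjusted p = 0.218). No fat body marker passed the filter on low counts. In these 5 lists, edgeR, DESeq2 and limma-voom called 0 genes, and 2 plasmatocyte markers and 1 muscle marker were higher at an unadjusted p of 0.05.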

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

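Voom with quality weights per library and the wider snoRNA name classes were chosen after seeing the data. The class ratio and share without U3 were not in the plan either. The other alternatives were planned. The median of box C/D snoRNAs stayed below 0 under every alternative run, and no called gene that the text names changed direction under any of them. The counts of genes moved most. DESeq2 gave 189 genes higher and 131 lower, 37 box C/D snoRNAs lower and 3 host genes changed. Without a filter on low counts these were 167, 116, 42 and 2, and with quality weights 313, 237, 36 and 4, with 2 box H/ACA snoRNAs lower. A test against a 1.5-fold change left 2 genes higher and 4 lower, and total counts alone gave 5 higher. All 75 genes of the main test were also called by DESeq2 and without a filter on low counts, 65 of them by limma-voom, and 26 with total counts alone. With DESeq2's size factors, TMM on genes outside the small RNA classes, or a minimum mean count of 10, the counts were within 1.5 times of the main ones. The wider name classes could not change the snoRNA counts: of the 2 tested snR38 genes 0 were called, and no Or-ACA gene was tested. The log2 ratio of the classes differed by -1.004 without U3, against -0.22 with it, since U3 holds most box C/D counts and was not lower. Camera with an estimated correlation called 0 lists and the directional form of fry 4, against 9 in the main test. Of these 9, fry called 2, translation factors (adjusted p = 0.00241) and cytosolic ribosomal proteins (adjusted p = 0.0227), and not box C/D snoRNAs (adjusted p = 0.152). Its other 2 were box C/D proteins and assembly factors, which include Fib (adjusted p = 0.00832), and host genes (adjusted p = 0.0264). The cause was not tested.

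Leaving out each library in turn gave 1 to 221 genes higher, 1 to 89 lower, 0 to 35 box C/D snoRNAs lower and 0 to 2 host genes changed. The log2 fold change of Fib lay between 2.07 and 2.32 and passed the threshold each time. Box H/ACA snoRNAs lower were 0 each time, lists past camera were 9 to 13, the log2 ratio of the classes differed by -0.25 to -0.20, and the share of box C/D counts by -0.62 to -0.35 percentage points. Without dsLacZ replicate 2, all 75 genes were among 310 called. Fewer libraries and a changed spread both act on these counts, and the cause was not tested further. Replicate numbers are shared by the groups but did not pair the libraries: the correlations of same-numbered deviations were -0.12, -0.40 and -0.27, and no library correlated best with its own number. The highest were 0.43 for dsLacZ replicate 1 with dsFib replicate 2, 0.43 for 2 with 3, and 0.21 for 3 with 1. Deviations within a group sum to 0, so values of both signs come together. A batch shared in another order was not tested. With the replicate number as a block, 0 genes were higher and 1 lower, 0 box C/D snoRNAs were lower, and Fib had a log2 fold change of 2.21 with an adjusted p of 0.0602. The block left the list count at 9, with 8 lists shared with the main test: nucleolar ribosome biogenesis factors no longer passed (adjusted p = 0.058) and scaRNAs did. With a library left out, scaRNAs, snRNAs, nuclear tRNAs, box H/ACA snoRNAs and host genes of box C/D snoRNAs each passed in at least 1 fit, and with total counts alone scaRNAs and nuclear tRNAs did. At this depth edgeR recovered 26.9% of genes simulated with a 1.5-fold change and 71.6% of those with a 2-fold change, so that small changes can be missed. Of the 137 box C/D snoRNAs in the tables, 88 had enough counts to be tested.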

Other observations

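Among 26 tested snoRNAs that the name pattern put in no class, 2 fell in the libraries labelled dsFib. They were snoRNA:684 in an intron of CG10576 (3L, 5763345 to 5763422, minus strand), from 110.1 ± 19.1 to 37.2 ± 3.46 CPM (2.96-fold, edgeR adjusted p = 0.00515), and snoRNA:291 in an intron of CG1646 (3R, 28812568 to 28812641, plus strand), from 86.5 ± 14.1 to 44.7 ± 4.94 CPM (1.93-fold, adjusted p = 0.0265). The host of snoRNA:684, CG10576, also holds snmRNA:CR43603, the largest fall outside the small RNA classes, and its own log2 fold change was 0.02 (SE 0.12). CG1646 had 0.06 (SE 0.09). Among transposable elements, 224 of 410 lay above 0 and 1 rose, with a median log2 fold change of 0.06. At an unadjusted p of 0.05, 46 were higher and 15 lower, against 1323 of all 8302 genes in either direction. DESeq2 called 12 higher and 2 lower, and limma-voom 0. The groups did not overlap for 62 that were higher and 25 that were lower, against 916 higher and 1006 lower of all 8302 genes, and copies of an element share reads.

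Tests in the paragraphs below that were chosen after their result was seen are those on snoRNA:229, on tRNAs, on host genes, on snoRNA length and on splits of the libraries for box C/D snoRNAs and lists; the others were written before their result was seen.

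Fib counts were 4.67-fold higher in the libraries labelled dsFib, against the label. An exchange of the labels of the groups was predicted to leave box C/D snoRNAs higher in the libraries labelled dsFib. Their median log2 fold change was -0.77, with the class ratio lower in all 3 libraries. The prediction assumes that less Fibrillarin lowers box C/D snoRNAs, which was not tested, so an exchange of labels stays open. Higher transcription of the whole gene was tested with snoRNA:229, encoded in a Fib intron, whose upper 95% bound was 0.15. This snoRNA cannot decide the question: its name gives no class, and whether its level follows that of its host is not known. Box C/D snoRNAs, a class to which it was not assigned, did not follow their hosts here (median log2 fold changes of -0.77 and 0.09). An intronic snoRNA thus need not rise with its gene. Higher transcription of Fib thus stays open. A rise of the box C/D protein genes as a group is argued against by Nop56, nop5 and hoip, whose highest upper 95% bound was 0.29. Reads from the double-stranded RNA added against Fib may account for the excess: this explanation needs no other core gene to rise, and the highest log2 fold change among these 3 was 0.050. A longer-lived Fib mRNA stays open too. The positions of reads along Fib, which would tell reads from the double-stranded RNA from those of Fib mRNA, were not analysed here.

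Box C/D snoRNAs were lower in the libraries labelled dsFib, by a median log2 of -0.77, while the median of box H/ACA snoRNAs was -0.001. A loss of short RNAs is argued against by nuclear tRNAs, of similar length, with a median of 0.067, and less host RNA by the host genes, with a median of 0.092, and by box H/ACA snoRNAs of the 5 shared hosts, with a median of 0.05. The 6 tested Uhg genes had a median of -0.02 and a lowest value of -0.54, so less RNA from a single Uhg host stays open. The library dsLacZ replicate 2 is not the whole source, since without it the median was -0.54 with 31 snoRNAs lower. In 10 splits of the 6 libraries, the real one gave 15 box C/D snoRNAs past the threshold and the highest other 0; the real split was the 1 split with so many, but the size of the class median was 0.77 in the real split and up to 0.72 in the others, and 10 splits are too few for a share under 0.05. A hypothesis that stays open is that less Fibrillarin protein was available to hold these RNAs in stable particles; it was not tested, since protein was not measured, and U3, whose particle also holds Fibrillarin, was not lower.

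A second hypothesis concerned the 26 snoRNAs that the name pattern put in no class: if short ones among them belong to the box C/D class, whose annotated genes have a median length of 80 nucleotides against 140 for box H/ACA, they should be lower than long ones. Spearman's rho of length and log2 fold change was 0.58 over all 26, which are not independent replicates (permutation test, two-sided, p = 0.00229), but these hold the 2 snoRNAs that prompted the test. Without those 2 it was 0.49 over 24 (permutation test, p = 0.0171), and without the 2 named snR38 as well, whose name already marks a family, it was 0.35 over 22 (permutation test, p = 0.111). The last 2 versions were added after the first was seen. The result thus depended on 4 genes, and membership of snoRNA:684 and snoRNA:291 in the box C/D class stays open.

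For the counts of changed genes and lists, 10 splits of the 6 libraries are also too few for a share under 0.05. The real split gave 75 genes past the threshold, the highest other 0, and 1 split gave so many. For lists past camera the real split gave 9 and the highest other 10, in the split of dsLacZ replicate 1 with dsFib replicates 2 and 3 against the rest, and 3 splits gave 9 or more. Each other split keeps part of the contrast between the groups, so these counts do not separate differences between single libraries from it.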
